A study of Homo sapiens with 18 samples.

How the data were processed

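RNA from sorted, green fluorescent NCI-H1299 cells was hybridized 40 hours after transfection to Affymetrix Gene arrays, which carry probes along each transcript. The 18 arrays were grouped by their titles into 6 groups of 3: empty vector, WTp53 and ΔNp53:WTp53 in experiments 0, 4 and 5 (the first set), and empty vector, WTp53 and tethered WTp53 in experiments d, e and f (the second set). For the tethered arrays the transfection field reads ΔNp53:WTp53, against their title and description; the title was used. The series describes experiments 0, 4 and 5 as independent transfections. It calls d, e and f control experiments without stating whether they were independent transfections, so the source of the variation between those arrays is not known. The main fit shares a spread over both sets. Its p-values therefore measure differences beyond that shared spread, not beyond the variation within either set. Fits of each set alone are given as alternatives.

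The values are log2 intensities deposited by the authors, who normalized them with RMA (background correction, quantile normalization and summary per probe set) in Affymetrix Expression Console, in versions that the labels do not state. The 2 sets were processed apart: the first has array medians from 4.89 to 4.97 and 6 decimals, the second array medians from 7.01 to 7.07 and 2 decimals. Levels were therefore never compared between the sets, and questions across sets were put only as differences of within-set effects. No signal over background was derived, and the number of arrays limits the precision.

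The table holds 33297 probe sets. The probe table pairs 19460 of them with exactly 1 gene symbol and 1754 with several, and does not list 12083. Probe sets with 1 symbol were used, and for the 769 genes with several the probe set with the highest mean was taken, which left 18417 genes; 18392 of these symbols are in the current gene table and 0 symbols were changed. Positions on a genome were not used. No filter on dim genes was applied.

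In R 4.3.3, limma 3.58.1 was fitted to all 18 arrays with a mean per group (12 residual degrees of freedom). There were 6 pairwise comparisons within the sets and 3 differences between such effects, each two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. A single comparison of 3 arrays with 3 cannot fall under an exact permutation p of 0.1, so no exact test could pass. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists of a comparison, and again with camera at an estimated correlation and with fry. Of 549 list members 505 were measured and 44 were not. The lists were 3 of p53 targets, the G2/M, G1/S and replication-dependent histone genes, mTOR, IGF and insulin signalling, oxidative phosphorylation, mitochondrial biogenesis and dynamics, integrated stress response, glycolysis and pentose phosphate, sterol and fatty acid synthesis, interferon-stimulated genes, inflammatory secreted factors, heat shock and unfolded protein response, immediate-early genes, progeroid syndrome genes, and markers of leukocytes, of fibroblasts and endothelium, and of lung epithelium. Groups, comparisons, lists and the rule for named genes were fixed before the data were examined.

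Genes were named by that rule: CDKN1A and MDM2 in every comparison, per pairwise comparison the 8 largest rises and 8 largest falls among genes past the threshold that moved the same way in all 3 same-experiment pairs, up to 4 members of each list with the smallest p, and the 5 smallest p in each difference of effects. The probe set of the transfected gene, planned as a check of the labels, is not reported here.

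Whether the experiment label pairs arrays was checked from correlations of residuals between arrays of different groups. In the first set all 9 same-experiment correlations were above 0.1 (0.11 to 0.57), and 6 of 9 were the highest of their kind. Those of experiment 0 were 0.37, 0.28 and 0.57, against at most −0.17 with other experiments. Those of experiment 5 were 0.15, 0.11 and 0.29, below the highest with another experiment (0.23, 0.20 and 0.35). The pairing thus rests mainly on experiment 0, and blocked values are given. In the second set they ran from −0.04 to 0.13 (5 of 9 highest), so the letters were treated as labels only.

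The test was tried on simulated data with independent genes and, for each gene, the spread shared by all groups in the fit. It therefore did not try unequal spread between groups or correlated genes. Of 50 genes shifted at each size, 20.0%, 86.0%, 96.0% and 100.0% were called at 1.2-, 1.5-, 2- and 4-fold for ΔNp53:WTp53 against WTp53, with 5 of 156 calls false (3.2%). For tethered WTp53 against WTp53 the shares were 10.0%, 84.0%, 98.0% and 100.0%, with 10 of 156 calls false (6.4%). A list shifted by −0.15 was called in both and 0 other lists were. The correlation expected from shared vector arrays was found from 20 simulations without effects.

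Alternatives were the experiment as a block (8 residual degrees of freedom), array weights, a trended and robust prior, a threshold of 0.01, a minimum of 1.5-fold, each set alone (6 residual degrees of freedom), only the 2 groups compared (4), joint quantile normalization, centring on array medians, leaving out the genes in the lowest tertile of mean value, every probe set, and leaving out each array in turn. Leaving out experiment 0, and fitting each set alone for the lists, were added after seeing the data.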

Results

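Gene expression was measured on 18 Affymetrix Gene arrays in NCI-H1299 cells, a lung carcinoma line that lacks p53, 40 hours after transfection with plasmids that also encode green fluorescent protein. Fluorescent cells were sorted before RNA extraction. The arrays form 2 sets of 9 that were normalized separately. The first set holds empty vector, wild-type p53 (WTp53) and ΔNp53:WTp53, which combines WTp53 with the N-terminally shortened isoform ΔNp53, each in experiments 0, 4 and 5. The second set holds empty vector, WTp53 and a tethered WTp53 construct, each in experiments d, e and f, which the series calls control experiments. Every group had 3 arrays, and this number limits the precision. The titles and descriptions of the tethered arrays name tethered WTp53, whereas their transfection field names ΔNp53:WTp53; they were grouped by title, so statements on the tethered construct rest on those titles.

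Array medians lay between 4.89 and 4.97 (log2) in the first set and between 7.01 and 7.07 in the second, so levels were compared within a set. Within groups the correlation across genes was 0.9830 to 0.9986, and genes are not independent replicates. The median standard deviation of a gene between replicates was 0.151 for ΔNp53:WTp53, 0.104 for the vector and 0.109 for WTp53 of the first set, and 0.049 to 0.069 in the second set. Changes below are log2 differences ± the standard error of the limma fit, with n = 3 arrays per group and 18417 genes tested. Genes named for the size of their change moved the same way in all 3 pairs of arrays that share an experiment label.

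WTp53 against empty vector in the first set asks which transcripts respond when p53 is returned to these cells. The known p53 targets for cell cycle arrest and feedback rose together. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 24.6-fold, from 5.27 ± 0.52 to 9.89 ± 0.12 (log2 mean ± SD, n = 3), by 4.62 ± 0.21 (limma adjusted p = 1.20e-10). MDM2, the ubiquitin ligase that limits p53, rose by 3.41 ± 0.11, SESN1, a sestrin of the oxidative stress response, by 3.32 ± 0.10, and GDF15, a secreted stress cytokine, by 2.96 ± 0.11. Of 27 measured members of this list 24 rose (25 adjusted over the list alone) and 0 fell, with a median change of 1.46 (camera adjusted p = 1.48e-16, and adjusted p = 0.0431 with an estimated correlation). The list median within experiments 0, 4 and 5 was 1.32, 1.31 and 1.17. Of 21 apoptosis targets 16 rose (17 adjusted over the list alone) and 1 fell (camera adjusted p = 1.94e-09, adjusted p = 0.0478 with an estimated correlation). They included TP53I3 (3.70 ± 0.13), APAF1, the scaffold of the apoptosome (3.20 ± 0.13), and the death receptor FAS (1.97 ± 0.10). Of 21 targets in DNA repair and metabolism 14 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 1.85e-06, adjusted p = 0.0818 with an estimated correlation). Among them DDB2, which recognizes ultraviolet damage, rose by 1.58 ± 0.07 and the translesion polymerase POLH by 1.90 ± 0.11. The largest rises of all genes were FAM13C (4.82 ± 0.10), CDKN1A, CYFIP2 (4.20 ± 0.15), KITLG, the ligand of the receptor KIT (4.19 ± 0.20), the phosphodiesterase PDE3A (4.08 ± 0.19), RRAD (4.00 ± 0.20) and the matrix proteoglycan VCAN (3.97 ± 0.22).

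Histone and DNA replication genes moved down with WTp53. Of 15 replication-dependent histone genes 11 fell and 1 rose, the same adjusted over the list alone, with a median of −0.86 (camera adjusted p = 1.95e-05, adjusted p = 0.0818 with an estimated correlation); H4C8 fell by 1.87. Of 28 G1/S and replication genes 17 fell (19 adjusted over the list alone) and 2 rose (camera adjusted p = 0.00227, adjusted p = 0.63 with an estimated correlation). Their members split at cyclin E, which drives entry into S phase: CCNE2 changed by −1.49 ± 0.25 and CCNE1 by 1.01 ± 0.09. The G2/M list was not called by camera or fry (5 fell and 3 rose of 29, camera adjusted p = 0.413), although CDK1, the mitotic kinase, fell by 2.58. The largest falls were ANKRD1 (−3.38 ± 0.17), CALHM4 (−3.10 ± 0.26), the zinc finger genes ZNF221 (−2.83 ± 0.15) and ZFP30 (−2.72 ± 0.19), and FBXO5, an inhibitor of the anaphase-promoting complex (−2.68 ± 0.38). Of 28 amino acid and integrated stress response genes 13 fell and 4 rose, also adjusted over the list alone, among them asparagine synthetase ASNS (−1.40 ± 0.11) and the cystine transporter SLC7A11 (−1.66 ± 0.19; list camera adjusted p = 0.00409, adjusted p = 0.405 with an estimated correlation). Of 21 heat shock and unfolded protein response genes 12 rose and 2 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.00227, adjusted p = 0.378 with an estimated correlation), EDEM1 by 1.48 ± 0.10. Of 24 IGF and insulin signalling genes 14 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0195, adjusted p = 0.405 with an estimated correlation). The receptor IGF1R rose by 1.68 ± 0.13 and PIK3R1, a regulatory subunit of phosphoinositide 3-kinase, by 1.88 ± 0.16. Of 22 progeroid syndrome genes 12 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00755, adjusted p = 0.405 with an estimated correlation), the repair nuclease ERCC4 by 1.42. In all 3978 genes rose and 4074 fell at a limma adjusted p under 0.05, of which 742 rose and 559 fell at least 2-fold. With the experiment as a block 8424 genes were called in place of 8052, and 3381 of the 8052 changed at least 1.5-fold.

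ΔNp53:WTp53 against empty vector in the first set asks what the combination does in the same cells. The p53 targets rose here too. CDKN1A rose 12.9-fold, by 3.69 ± 0.21 (limma adjusted p = 1.03e-09), MDM2 by 3.09 ± 0.11 and PLK3, a stress-responsive polo-like kinase, by 3.55 ± 0.17. Of 27 arrest and feedback targets 22 rose (23 adjusted over the list alone) and 0 fell, with a median of 1.28 (camera adjusted p = 1.05e-14, adjusted p = 0.0653 with an estimated correlation), and their median in experiments 0, 4 and 5 was 1.01, 1.48 and 1.07. Of 21 apoptosis targets 16 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.71e-08, adjusted p = 0.0676 with an estimated correlation). Of 21 repair and metabolism targets 15 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 1.22e-06, adjusted p = 0.0949 with an estimated correlation). Genes of mitosis fell: of 29 G2/M genes 26 fell and 1 rose, also adjusted over the list alone, with a median of −1.19 (camera adjusted p = 2.55e-07, adjusted p = 0.434 with an estimated correlation). They included the kinase NEK2 (−1.30 ± 0.17), the kinetochore motor CENPE (−1.61 ± 0.23) and the spindle motor KIF11 (−1.52 ± 0.26). Their median was −0.41 in experiment 0, −1.35 in experiment 4 and −1.69 in experiment 5. Of 28 G1/S and replication genes 25 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 7.37e-07, adjusted p = 0.434 with an estimated correlation). Of 15 histone genes 11 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 1.89e-04, adjusted p = 0.159 with an estimated correlation).

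The series title names mitochondria, the mTOR pathway and progeroid changes. With the combination camera called the lists of mitochondrial biogenesis and of progeroid syndromes and not those of oxidative phosphorylation and mTOR, which fry called down (fry adjusted p = 0.00289 and 0.00265). Of 35 oxidative phosphorylation genes 14 fell and 4 rose (15 and 5 adjusted over the list alone, camera adjusted p = 0.0724, adjusted p = 0.605 with an estimated correlation). Of 34 genes of mitochondrial biogenesis and dynamics 21 fell and 5 rose (21 and 6 adjusted over the list alone, camera adjusted p = 0.00552, adjusted p = 0.279 with an estimated correlation). The import component TIMM44 fell by 0.99, whereas the coactivator PPARGC1A rose by 1.08 ± 0.12. Of 22 progeroid syndrome genes 15 fell and 2 rose, also adjusted over the list alone, with a median of −0.47 (camera adjusted p = 7.65e-04, adjusted p = 0.434 with an estimated correlation). The RecQ helicase BLM fell by 1.41 and the telomere protein TERF1 by 0.92. Of 24 IGF and insulin signalling genes 14 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 3.96e-04, adjusted p = 0.305 with an estimated correlation), with PIK3R1 at 2.37 ± 0.16 and IGF1R at 1.72 ± 0.13. Of 30 mTOR genes 15 fell and 6 rose (camera adjusted p = 0.214, adjusted p = 0.605 with an estimated correlation). PRKAA2, a catalytic subunit of the kinase AMPK, fell by 1.23 and STK11, the kinase upstream of AMPK, rose by 0.79 ± 0.07. The largest changes were rises of SLC4A11 (4.75 ± 0.29), FAM13C (4.63 ± 0.10), VCAN (4.58 ± 0.22) and the Notch ligand JAG2 (4.18 ± 0.25), and falls of ANKRD1 (−2.94 ± 0.17), FAM111B (−2.32 ± 0.41) and C5orf34 (−2.26 ± 0.26). In all 3880 genes rose and 4733 fell, of which 902 and 607 changed at least 2-fold. With the experiment as a block 8932 genes were called, and 3909 of the 8613 changed at least 1.5-fold. Both comparisons share the vector arrays: with no effect simulated, 20 simulations gave a correlation of 0.49 between their changes, against 0.91 observed, and the observed covariance of 0.2802 exceeded the simulated 0.0066 by 0.2737. Of the genes called, 2924 rose in both (838.1 by independent calls) and 3422 fell in both (1047.0 by independent calls). The simulations gave at most 0 shared calls, which is no baseline, since without effects hardly any gene is called. The numbers by independent calls do not allow for the shared vector arrays.

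**Figure D1:**
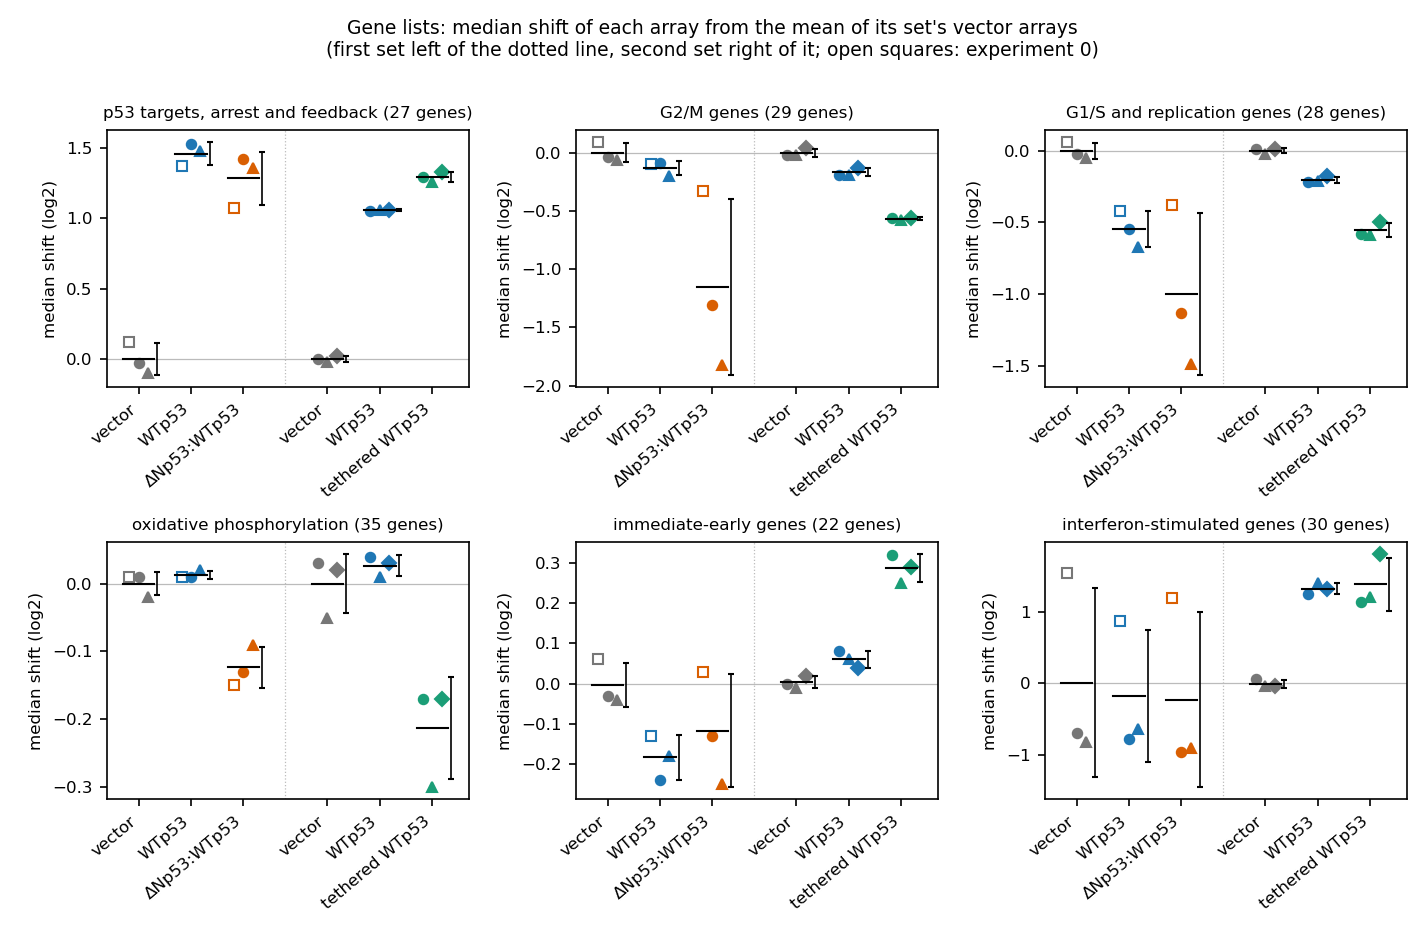
Median log2 shift of 6 gene lists in each array from the mean of the vector arrays of its set; lines are group means, bars 1 SD of 3 arrays, and open squares experiment 0. G2/M genes fell most with ΔNp53:WTp53 in experiments 4 and 5 (−1.31 and −1.82). In experiment 0 (−0.33) they fell by less than with tethered WTp53 (−0.58 to −0.56).

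ΔNp53:WTp53 against WTp53 asks how the combination differs from WTp53 alone. The part of the shortened isoform itself was not separated from other differences between the constructs. Genes of mitosis were lower with the combination: of 29 G2/M genes 21 fell (25 adjusted over the list alone) and 0 rose, with a median of −0.99 (camera adjusted p = 1.47e-13, adjusted p = 0.492 with an estimated correlation). Survivin BIRC5 fell by 0.93, the mitotic kinases AURKA and NEK2 by 1.31 and 1.10, and cyclin CCNB2 by 0.69. The G2/M median was −0.22 in experiment 0, −1.20 in experiment 4 and −1.54 in experiment 5. Of 28 G1/S and replication genes 9 fell (11 adjusted over the list alone) and 0 rose (camera adjusted p = 1.11e-05, adjusted p = 0.541 with an estimated correlation), with cyclin CCNA2 at −0.74 ± 0.15 and the ribonucleotide reductase subunit RRM2 at −0.77 ± 0.15; the list median was 0.04, −0.63 and −0.79 in experiments 0, 4 and 5. With the first set fitted alone 5 G2/M genes and 0 G1/S genes passed.

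Some p53 targets differed between the combination and WTp53, in both directions. CDKN1A was lower by 0.93 ± 0.21 (limma adjusted p = 0.00658), GDF15 fell by 1.23 and SESN1 by 0.49, whereas PLK3 rose by 1.27 ± 0.17; MDM2 differed by −0.31 ± 0.11, which did not pass (limma adjusted p = 0.0625) but did without ΔNp53:WTp53 of experiment 5. Of 27 arrest and feedback targets 6 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.0475, adjusted p = 0.568 with an estimated correlation). The apoptosis list and the repair and metabolism list were not called by camera or fry (camera adjusted p = 0.699 and 0.788). CHAC1, a glutathione-degrading enzyme induced by ATF4, rose 2.8-fold, by 1.51 ± 0.10 (limma adjusted p = 2.55e-07). With the lipoprotein receptor VLDLR (1.06 ± 0.10) it led the integrated stress response list, of which 8 of 28 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0035, adjusted p = 0.492 with an estimated correlation). Of 22 immediate-early genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 8.87e-05, adjusted p = 0.169 with an estimated correlation), among them the phosphatase DUSP6 (0.57 ± 0.07), JUNB (0.64 ± 0.09) and NR4A2 (1.17 ± 0.25). HYOU1 and HSPA5, which encode chaperones of the endoplasmic reticulum, fell by 0.75 and 0.69; HSPA5 did not pass with the first set fitted alone (limma adjusted p = 0.0586). They belong to a heat shock and unfolded protein list with 8 of 21 down and 2 up (12 and 4 adjusted over the list alone, camera adjusted p = 0.00561, adjusted p = 0.492 with an estimated correlation).

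Genes of the respiratory chain were lower by a small amount. Of 35 oxidative phosphorylation genes 10 fell and 3 rose, also adjusted over the list alone, with a median of −0.13 (camera adjusted p = 0.00263, adjusted p = 0.492 with an estimated correlation) and of −0.12, −0.15 and −0.12 in experiments 0, 4 and 5. The complex I subunits NDUFA2 and NDUFB3 fell by 0.53 and 0.52, and TFAM, which maintains mitochondrial DNA, by 0.53, although the mitochondrial biogenesis list was called by fry (fry adjusted p = 0.037) and not by camera (camera adjusted p = 0.197). The mTOR and progeroid lists were not called by either (camera adjusted p = 0.343 and 0.291). IRS1, an adaptor of the insulin receptor, rose by 1.14 ± 0.10 in an IGF list with 3 of 24 up and 1 down (8 and 1 adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.527 with an estimated correlation). In a sterol and fatty acid list with 6 of 21 down and 2 up (9 and 2 adjusted over the list alone, camera adjusted p = 0.0492, adjusted p = 0.64 with an estimated correlation), the desaturase FADS2 fell by 0.50. Of 14 leukocyte markers 2 fell, also adjusted over the list alone (camera adjusted p = 0.0492, adjusted p = 0.492 with an estimated correlation), CD79A by 0.32 and TYROBP by 0.29. The largest rise was CDKL2 (1.88 ± 0.21), followed by TMEM229A (1.51 ± 0.28), CHAC1 and RAB27B (1.41 ± 0.20). The largest falls were GDF9, a growth factor of the TGF-beta family (−2.62 ± 0.12, limma adjusted p = 2.44e-09), CLCA2 (−2.10 ± 0.22), the serpin SERPINB5 (−1.98 ± 0.12) and DAW1 (−1.75 ± 0.17).

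In all 1309 genes rose and 1384 fell with ΔNp53:WTp53 relative to WTp53, 45 and 62 of them at least 2-fold; 3291 genes were called with the experiment as a block and 549 of the 2693 changed at least 1.5-fold. With the first set fitted alone CDKN1A, SESN1, CCNA2, RRM2, HSPA5, NR4A2, FADS2, CD79A and TYROBP did not pass. With these 6 arrays alone CHAC1, RAB27B, IRS1, VLDLR, GDF15, GDF9, CLCA2, SERPINB5 and DAW1 were the genes named for this comparison that passed. The count depends on the spread used and on experiment 0: 449 genes passed with the first set fitted alone, 96 with these 6 arrays alone, 1785 without WTp53 of experiment 4, 4816 without ΔNp53:WTp53 of experiment 0 and 5450 without any array of experiment 0.

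WTp53 against empty vector in the second set repeats the first comparison on other arrays. The p53 targets rose again: CDKN1A by 3.13 ± 0.21 (limma adjusted p = 2.62e-08), MDM2 by 2.11 ± 0.11, SESN1 by 2.82 ± 0.10 and GDF15 by 2.60 ± 0.11. Of 27 arrest and feedback targets 22 rose (24 adjusted over the list alone) and 0 fell (camera adjusted p = 5.14e-29, adjusted p = 0.00461 with an estimated correlation). Of 21 apoptosis targets 13 rose (14 adjusted over the list alone) and 0 fell (camera adjusted p = 3.99e-13, adjusted p = 0.0146 with an estimated correlation). Of 21 repair and metabolism targets 12 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 6.33e-10, adjusted p = 0.0231 with an estimated correlation). Histone genes fell, 11 of 15 with 1 up, also adjusted over the list alone (camera adjusted p = 1.52e-06, adjusted p = 0.0485 with an estimated correlation). Outside this list the histone genes H4C2 and H3C7 changed by −2.31 ± 0.26 and −2.08 ± 0.30. Of 28 genes of glycolysis and the pentose phosphate path 18 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 1.83e-08, adjusted p = 0.141 with an estimated correlation). The glucose transporter SLC2A1 rose by 0.86 ± 0.10 and PFKFB4, a regulator of glycolytic flux, by 1.57 ± 0.21. Interferon-stimulated genes were higher with a median of 1.34: of 30 measured 4 rose (3 adjusted over the list alone) and 0 fell (camera adjusted p = 8.86e-05, adjusted p = 0.767 with an estimated correlation), CXCL10 by 2.86 ± 0.73 and IFIT3 by 1.91 ± 0.53. IFIT3 did not pass without single arrays of this comparison, the vector of d or f or WTp53 of e or f. With the second set fitted alone 24 of the list rose. The list medians were close within these groups, from −0.04 to 0.06 with the vector and from 1.25 to 1.41 with WTp53, and spanned −0.82 to 1.54 in the vector arrays of the first set, which enter the shared spread. Of 28 integrated stress response genes 10 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0424, adjusted p = 0.767 with an estimated correlation), ASNS by 0.66. The G2/M and G1/S lists were not called by camera or fry (camera adjusted p = 0.248 and 0.172). In all 1940 genes rose and 1663 fell, 280 and 59 of them at least 2-fold; 53.8% of the calls were up, against 41.6% with each array centred on its median. With the second set fitted alone 6769 genes passed, 7061 with these 6 arrays alone, 5740 without experiment 0 of the first set, which enters only through the shared spread, and 1167 of the 3603 changed at least 1.5-fold.

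Across all genes the log2 changes with WTp53 in the 2 sets, which share no array, correlated with Pearson's r = 0.79 and Spearman's rho = 0.66, and genes are not independent replicates. Of the genes called, 1576 rose in both (419.0 by independent calls), 1448 fell in both (367.9 by independent calls) and 30 (1.0%) changed in opposite directions. The slope of the second on the first set was 0.50 over the genes called in the first set, whether or not they were called in the second. The difference between the sets was itself called for 2300 genes, 1093 up and 1207 down, among them MDM2, whose rise was larger in the first set by 1.30 ± 0.15.

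Tethered WTp53 against empty vector in the second set raised p53 targets as well. GDF15 rose by 3.82 ± 0.11, PLK3 by 3.71 ± 0.17 and CDKN1A by 3.22 ± 0.21 (limma adjusted p = 7.17e-09). Outside the p53 target lists FAM13C rose by 4.34 ± 0.10 and cyclin CCNA1 by 3.77 ± 0.17. Of 27 arrest and feedback targets 23 rose (24 adjusted over the list alone) and 0 fell (camera adjusted p = 1.32e-20, adjusted p = 0.019 with an estimated correlation). Of 21 apoptosis targets 15 rose (16 adjusted over the list alone) and 0 fell (camera adjusted p = 9.08e-11, adjusted p = 0.0259 with an estimated correlation). Of 21 repair and metabolism targets 13 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.30e-09, adjusted p = 0.0259 with an estimated correlation). Cell division genes fell: 20 of 28 G1/S genes with 1 up (22 and 1 adjusted over the list alone, camera adjusted p = 4.52e-05, adjusted p = 0.456 with an estimated correlation), 11 of 29 G2/M genes with 0 up, also adjusted over the list alone (camera adjusted p = 1.28e-04, adjusted p = 0.49 with an estimated correlation), and 11 of 15 histone genes with 1 up (12 and 1 adjusted over the list alone, camera adjusted p = 9.16e-06, adjusted p = 0.0723 with an estimated correlation). Of 28 glycolysis genes 20 rose and 3 fell (21 and 4 adjusted over the list alone, camera adjusted p = 2.41e-06, adjusted p = 0.189 with an estimated correlation). Of 30 interferon-stimulated genes 7 rose (6 adjusted over the list alone) and 0 fell (camera adjusted p = 3.08e-04, adjusted p = 0.492 with an estimated correlation). Of 22 immediate-early genes 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.114 with an estimated correlation). JUNB rose by 1.52 ± 0.09 and the RNA-binding ZFP36 by 1.81 ± 0.18.

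Oxidative phosphorylation, mitochondrial, mTOR and progeroid lists shifted down with the tethered construct, and the IGF list up. Of 35 oxidative phosphorylation genes 19 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 2.51e-04, adjusted p = 0.236 with an estimated correlation). Of 34 genes of mitochondrial biogenesis and dynamics 19 fell and 6 rose, also adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.149 with an estimated correlation), SSBP1, the mitochondrial single-strand DNA-binding protein, by 0.70. Of 30 mTOR genes 12 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0457, adjusted p = 0.366 with an estimated correlation): RPTOR, a core subunit of mTOR complex 1, fell by 0.59, whereas DDIT4, an inhibitor of that complex, rose by 1.99 ± 0.16. Of 22 progeroid genes 12 fell and 3 rose (14 and 3 adjusted over the list alone, camera adjusted p = 0.00208, adjusted p = 0.397 with an estimated correlation), the lamin protease ZMPSTE24 by 0.47. Of 24 IGF genes 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0266, adjusted p = 0.456 with an estimated correlation). In all 2781 genes rose and 3434 fell, 574 and 161 at least 2-fold; 44.7% of the calls were up, against 31.9% with each array centred on its median, and 2263 changed at least 1.5-fold. The second set's vector arrays are shared: 20 simulations without effect gave a correlation of 0.50 between its 2 comparisons against 0.89 observed, and a covariance of 0.0067 against 0.1295, a difference of 0.1228. Genes called up in both numbered 1618 (292.9 by independent calls) and down in both 1415 (310.1 by independent calls). The at most 0 shared calls of the simulations are no baseline, since without effects hardly any gene is called. The numbers by independent calls do not allow for the shared vector arrays.

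**Figure D2:**
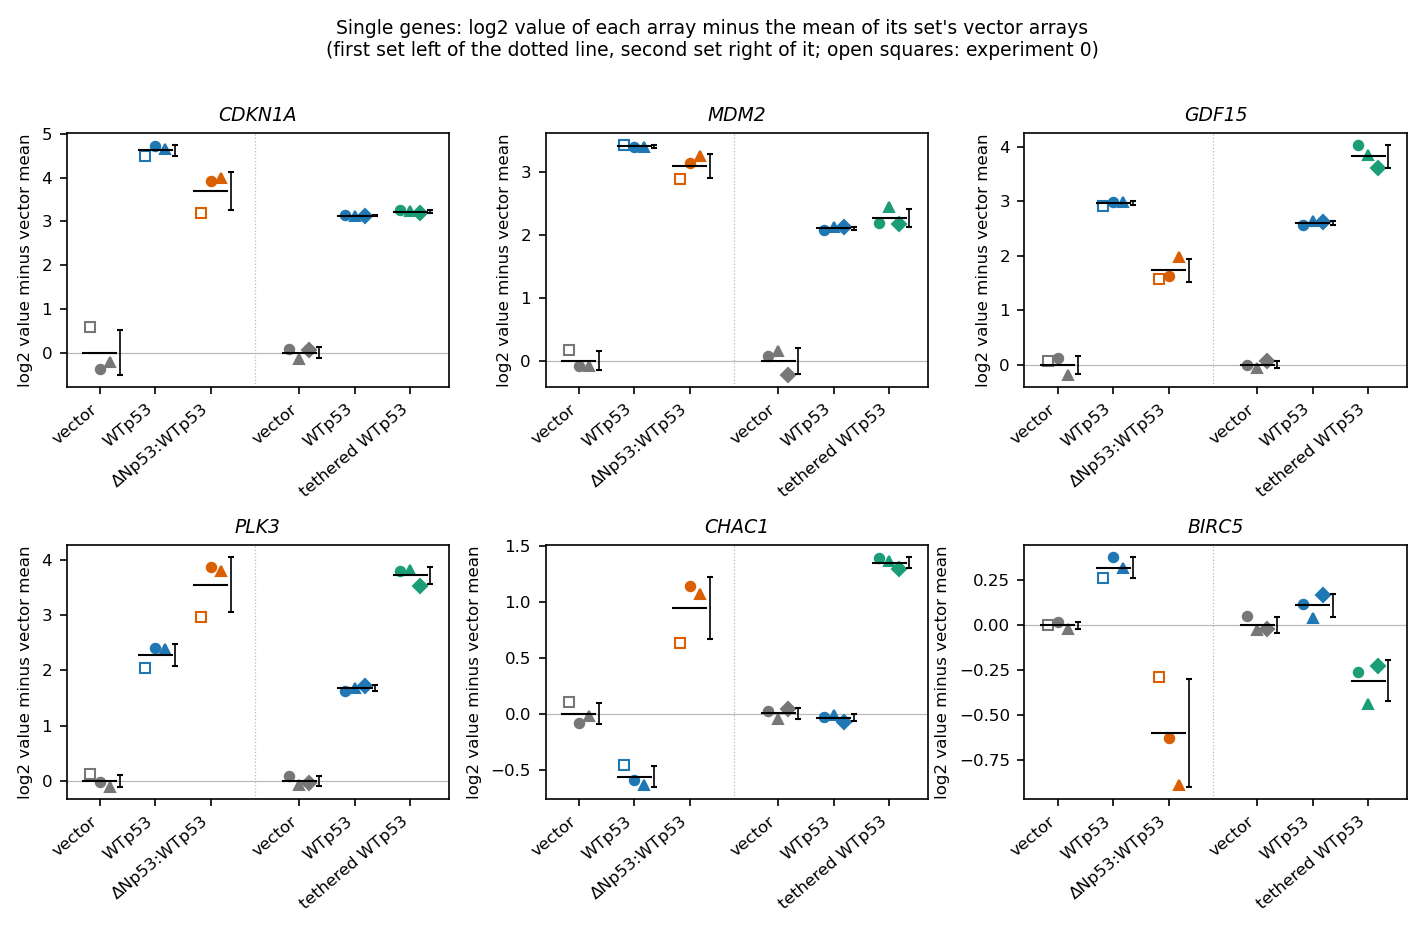
Log2 value of 6 genes in each array minus the mean of the vector arrays of its set; lines are group means, bars 1 SD of 3 arrays, and open squares experiment 0. CDKN1A and MDM2 rose with every p53 construct, GDF15 was lower with ΔNp53:WTp53 and higher with tethered WTp53 than with WTp53, and CHAC1 was higher with both than with WTp53.

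Tethered WTp53 against WTp53 compares the constructs within the second set, with the tethered arrays taken by their titles. CDKN1A differed by 0.09 ± 0.21 (limma adjusted p = 0.837) and MDM2 by 0.17 ± 0.11 (limma adjusted p = 0.378), neither of which passed. These standard errors use the spread shared with the first set. By array, CDKN1A was 11.77 to 11.83 with the tethered construct and 11.70 to 11.72 with WTp53, and MDM2 12.64 to 12.90 and 12.53 to 12.58. PLK3 rose by 2.04 ± 0.17 (limma adjusted p = 2.03e-05), RAB27B by 1.70 ± 0.20, the transcription factor IRF1 by 1.39 ± 0.28, CHAC1 by 1.38 ± 0.10, the receptor kinase MERTK by 1.29 ± 0.12 and GDF15 by 1.22 ± 0.11. Respiratory chain genes were lower: of 35 oxidative phosphorylation genes 12 fell and 0 rose (19 and 1 adjusted over the list alone), with a median of −0.21 (camera adjusted p = 7.25e-12, adjusted p = 0.0512 with an estimated correlation). NDUFA2 fell by 0.67 and NDUFB3 by 0.55. Of 34 mitochondrial biogenesis genes 9 fell and 1 rose (10 and 2 adjusted over the list alone, camera adjusted p = 2.69e-05, adjusted p = 0.078 with an estimated correlation), TFAM by 0.53. Of 22 immediate-early genes 10 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.0503 with an estimated correlation), with the phosphatases DUSP1 at 0.76 ± 0.12 and DUSP5 at 0.72 ± 0.09. Cell cycle lists shifted down with few single calls: the G1/S median was −0.35 with 1 of 28 down (0 adjusted over the list alone, camera adjusted p = 2.65e-06, adjusted p = 0.551 with an estimated correlation), which was thymidylate synthase TYMS (−0.22 ± 0.06). The G2/M median was −0.37 with 3 of 29 down, also adjusted over the list alone (camera adjusted p = 2.45e-05, adjusted p = 0.551 with an estimated correlation), namely CCNB2 (−0.53 ± 0.10), PTTG1 (−0.28 ± 0.07) and BIRC5 (−0.42 ± 0.11). With the second set fitted alone 25 G1/S and 26 G2/M genes fell.

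p53 target lists were slightly higher with the tethered construct. Of 27 arrest and feedback targets 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.551 with an estimated correlation). Of 21 apoptosis targets 4 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00305, adjusted p = 0.412 with an estimated correlation), APAF1 by 0.68 ± 0.13. Of 21 repair and metabolism targets 5 rose (6 adjusted over the list alone) and 0 fell (camera adjusted p = 0.00246, adjusted p = 0.412 with an estimated correlation), DDB2 by 0.49 ± 0.07. The IGF, progeroid, mTOR and sterol lists were called with at most 3 members past the test on either side (camera adjusted p = 0.0187, 0.0187, 0.0361 and 0.0389, adjusted p = 0.551, 0.551, 0.446 and 0.653 with an estimated correlation). They were IGF1R (0.50 ± 0.13), IGFBP4 (0.41 ± 0.12) and AKT2 (−0.25 ± 0.06) for IGF, and the lamin LMNB2 (−0.34 ± 0.10) for the progeroid list. For mTOR 2 rose and 3 fell, among them DDIT4 (0.62 ± 0.16), RPTOR (−0.33 ± 0.08), RHEB (−0.26 ± 0.07) and RRAGB (−0.36 ± 0.10). For the sterol list they were ACACA (0.33 ± 0.08) and FASN (−0.33 ± 0.08), which act in fatty acid synthesis. The largest falls were noncoding: LIMD1-AS1 (−1.77 ± 0.33), the vault RNA VTRNA1-2 (−1.43 ± 0.22) and the small nucleolar RNAs SNORD114-3 (−1.42 ± 0.19) and SNORD4B (−1.29 ± 0.16). In all 780 genes rose and 1075 fell, 22 and 8 at least 2-fold; 42.0% of the calls were up, against 28.2% with each array centred on its median. BIRC5, PTTG1, TYMS and the named members of the IGF, progeroid, mTOR and sterol lists did not pass without 1 or more of the single arrays. With the second set fitted alone 5970 genes passed, 5274 with these 6 arrays alone, 4549 without experiment 0 of the first set, and 293 of the 1855 changed at least 1.5-fold. The count was 797, 916 and 972 without WTp53 of experiments f, d and e, and 870 and 916 without tethered WTp53 of d and e.

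The differences of ΔNp53:WTp53 and of tethered WTp53 from the WTp53 of their own sets share no array. Across genes they correlated with Pearson's r = 0.42 and Spearman's rho = 0.35. Genes called in both rose together in 295 cases (55.4 by independent calls), fell together in 338 (80.8 by independent calls) and moved apart in 32 (4.8%). The test of the difference between these effects called 544 genes, 283 up and 261 down; 52.0% were up, against 71.1% with each array centred on its median. GDF15 stood apart, by −2.45 ± 0.16 (limma adjusted p = 5.60e-07), since it was lower with ΔNp53:WTp53 and higher with tethered WTp53. GDF9 (−1.63 ± 0.17), BEND2 (−1.39 ± 0.13), PCSK5 (−1.19 ± 0.12) and INPP5D (−1.03 ± 0.11) were lower with ΔNp53:WTp53 by this test, and IRS1 (0.99 ± 0.14) and VLDLR (1.05 ± 0.14) higher. The G2/M list was lower by a median of −0.64 (camera adjusted p = 8.64e-05, adjusted p = 0.566 with an estimated correlation), with 0 of 29 genes past the test of the difference, also adjusted over the list alone. The G1/S list was not called by camera or fry (camera adjusted p = 0.727). The arrest and feedback list differed by a median of −0.21 (camera adjusted p = 8.64e-05, adjusted p = 0.411 with an estimated correlation), and the oxidative phosphorylation list differed by 0.08 (camera adjusted p = 0.00875, adjusted p = 0.416 with an estimated correlation). Also called lower were heat shock and unfolded protein genes (camera adjusted p = 0.00262), p53 apoptosis targets (0.0038), p53 repair and metabolism targets (0.00605) and fibroblast and endothelial markers (0.0293), and higher histone genes (0.0198), mitochondrial biogenesis (0.0399) and the integrated stress response (0.0399). With an estimated correlation none of these 7 was called (adjusted p from 0.411 to 0.566). Construct and set cannot be told apart in this test, and its count was 1318 without ΔNp53:WTp53 of experiment 0, 851 without that of experiment 5 and 200 without WTp53 of experiment f. It was 917, 336 and 338 without WTp53 of experiments 0, 4 and 5, 258 and 235 without WTp53 of d and e, 208, 348 and 348 without tethered WTp53 of d, e and f, and 2570 without experiment 0.

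Relative to the empty vectors, the effects of ΔNp53:WTp53 and tethered WTp53 differed for 1090 genes, 629 up and 461 down. GDF15 (−2.09 ± 0.16) and ANGPTL4, a lipase inhibitor induced by hypoxia (−2.28 ± 0.21), rose less with ΔNp53:WTp53, and ITGA4 (0.92 ± 0.09) and ARVCF (1.39 ± 0.14) were higher. By camera 7 lists differed. Of 22 immediate-early genes 5 were lower and 0 higher (10 and 2 adjusted over the list alone), with a median of −0.34 (camera adjusted p = 9.56e-05, adjusted p = 0.143 with an estimated correlation), and this was the 1 list that fry also called (fry adjusted p = 8.26e-04). The interferon-stimulated list differed by a median of −1.36 (camera adjusted p = 9.56e-05), the G2/M list by −0.56 (camera adjusted p = 9.56e-05) and the G1/S list by −0.36 (camera adjusted p = 6.25e-04), each with 0 members past the test, also adjusted over the list alone. Of 28 glycolysis genes 7 were lower and 2 higher (11 and 5 adjusted over the list alone, camera adjusted p = 0.00345). Of 24 IGF genes 5 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 5.85e-04), and of 21 apoptosis targets 2 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.0346). For these 6 lists the adjusted p was 0.788 with an estimated correlation. The count was 1830 with the experiment as a block and 5407 without experiment 0. It was 4312, 521 and 620 without ΔNp53:WTp53 of experiments 0, 4 and 5, 639 and 694 without the vector of experiments 4 and 5, 494, 509 and 536 without the vector of d, e and f, and 537, 623 and 629 without tethered WTp53 of d, e and f.

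**Figure D3:**
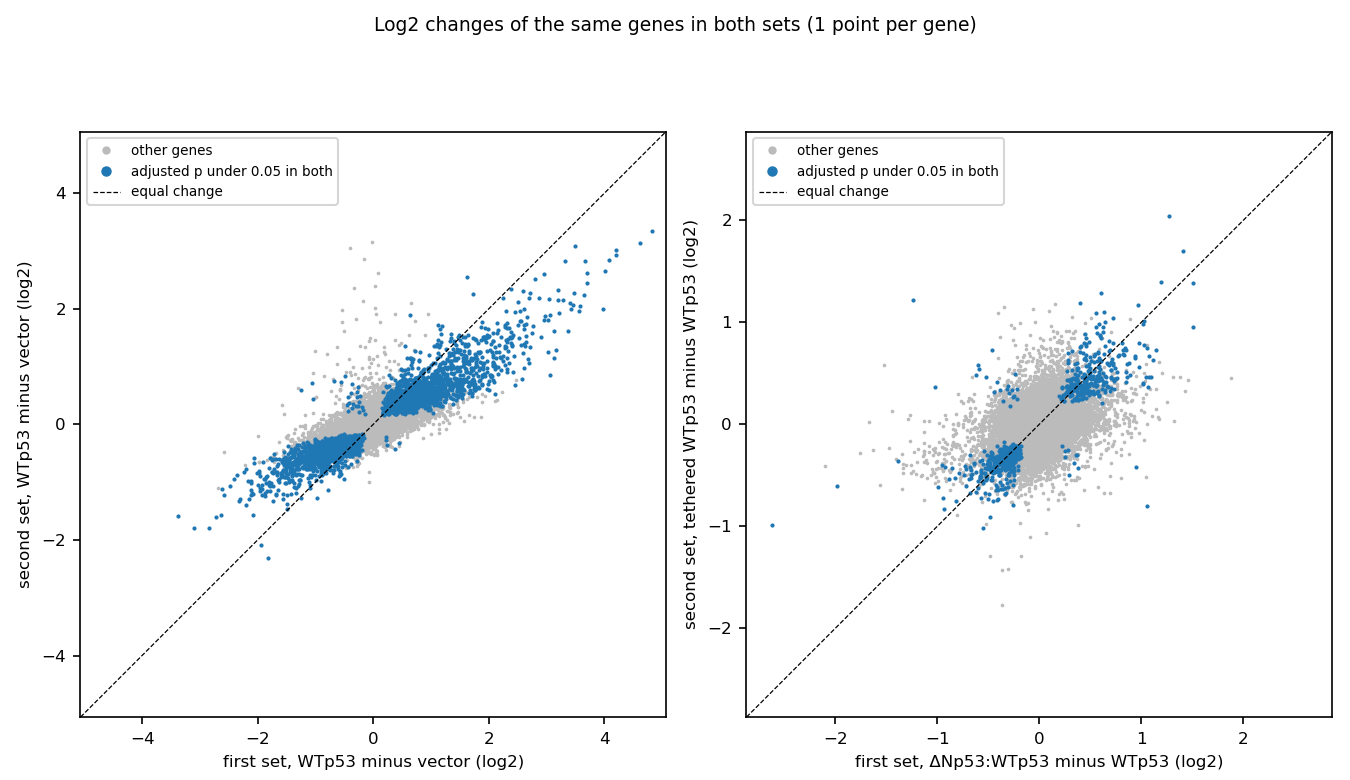
Log2 changes of 18417 genes, 1 point per gene, with the first set on the x axis and the second on the y axis; blue points passed a limma adjusted p under 0.05 in both and the dashed line marks equal change. WTp53 minus vector (left) correlated at 0.79. Its slope over the genes called in the first set (0.50) was flatter than the line of equal change. The differences of the other constructs from WTp53 (right) correlated at 0.42.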

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

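The tests of interferon-stimulated genes and of the scale of the second set below were chosen after the result was seen; the splits of the samples were planned. All results here concern the difference of the WTp53 effect between the sets, which was tested by limma as a difference of effects.

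The WTp53 effect differed between the sets for 2300 genes. CYP27C1 rose by 3.12 in the first set and 1.14 in the second, a difference of 1.98 ± 0.17 (limma adjusted p = 4.19e-05). PROKR1 rose by 3.38 and 1.62, a difference of 1.75 ± 0.16, and FAM13C by 4.82 and 3.35, a difference of 1.47 ± 0.14. ANGPTL4 changed by −0.17 in the first set, which did not pass, and rose by 2.14 in the second, a difference of −2.31 ± 0.21. STX11 fell by 1.21 in the first set and changed by −0.02 in the second, which did not pass, a difference of −1.19 ± 0.11. Of 100 splits that exchanged arrays of matching groups between the sets, drawn from 200, 1 gave as many genes, the real split, and the highest other gave 0, but those splits part the pairs of the first set. Among the 28 splits that keep these pairs, run after that was seen, 1 gave as many genes, the real split, and the highest other gave 0. That is a share of 0.0357, the lowest that 28 splits allow. The sets differ in spread and scale, so exchanging their arrays cannot exclude chance for the count. The count was 3185 at most without single arrays; it was 1474 and 1344 without WTp53 of experiments 4 and 5, 1359, 1272 and 1526 without the vector of d, e and f, and 1444, 1293 and 1307 without WTp53 of d, e and f.

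Of the 21 lists 14 differed. More positive in the first set were p53 arrest and feedback targets (camera adjusted p = 4.55e-04), p53 apoptosis targets (7.27e-05), p53 repair and metabolism targets (0.0268), heat shock and unfolded protein genes (1.55e-04), IGF and insulin signalling (0.0106), and fibroblast and endothelial markers (0.0394). More positive in the second set were the integrated stress response (0.0106), G1/S genes (0.0097), glycolysis (0.0186), immediate-early genes (0.00433), interferon-stimulated genes (0.00105), mitochondrial biogenesis (0.0268), progeroid genes (0.0201) and histone genes (0.0186). With an estimated correlation 0 of the 14 were called, with adjusted p from 0.26 to 0.584. The number of lists was 8 without the vector array of experiment 0. Among glycolytic genes PDK1 differed by −1.33 ± 0.22, HK2 by −1.28 ± 0.23 and the glucose transporter SLC2A3 by −1.34 ± 0.25, all higher with WTp53 in the second set by this test.

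Effects were smaller in the second set for 2150 of the 2300 genes, and 582 of the 2300 had opposite signs in the 2 sets. A narrower log2 scale after the separate normalization would not turn a sign. Most of the 582 were not called in the second set, so their sign there is uncertain. For those that were called there, a narrower scale as the whole cause is argued against. After joint quantile normalization 51.8% of the genes (1191) stayed called in the same direction. This cannot decide on the scale, since that step matches whole arrays and not the size of effects. It replaced an earlier test, whose outcome had fitted a narrower scale: fewer than 10% of the genes, 150 (6.5%), had the larger effect in the second set. For the 1109 genes whose call ended, the median absolute difference went from 0.50 (median SE 0.14) to 0.38 (median SE 0.13). Their calls thus ended with a smaller difference. A narrower scale stays open for these and for the other genes with the same sign in both sets. Interferon-stimulated genes were higher with WTp53 by 1.21, 1.38 and 1.31 in the median in experiments d, e and f, and differed by −0.47, −0.02 and 0.04 in experiments 0, 4 and 5. A rise with WTp53 in any transfection is argued against, since the highest median in experiments 4 and 5 was 0.04. Vector arrays of the first set alone spanned 2.36 in the list median. Relative to the mean of these vector arrays, the medians in experiment 0 were 1.54 with the vector, 0.88 with WTp53 and 1.19 with ΔNp53:WTp53. In experiments 4 and 5 they ran from −0.96 to −0.64, so in the first set the level went with the experiment and not with the plasmid. A response to the transfection or to a plasmid preparation stays open, and preparation cannot be told apart from construct in the second set. No biological explanation was tested, since the labels name no difference between the WTp53 cells of the sets.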

How the results depend on the processing

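The set-alone tests of the lists and the tests without experiment 0 were chosen after seeing the data. Lettered in order, A to C are WTp53, ΔNp53:WTp53 and ΔNp53:WTp53 against WTp53 (first set), D to F are WTp53, tethered WTp53 and tethered against WTp53 (second set), and G to I are the differences of effects relative to WTp53, of WTp53 between sets, and relative to the vectors. Among 102 counts of genes under other settings 67 stayed within 1.5 times the reported value.

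The experiment as a block moved only the count of I by over 1.5 times, to 1830. Each set alone gave 449 for C, 6769 for D and 5970 for F, and only the 2 groups gave 96, 7061 and 5274; the median spread was 0.151 in ΔNp53:WTp53 and at most 0.069 in the second set, so sharing 1 spread moves these counts. All 449 were among the 2693. Array weights gave 5626, 7767, 6618, 3332, 5646 and 5721 for C, D and F to I; ΔNp53:WTp53 of experiment 0 had the lowest weight, 0.12. A threshold of 0.01 gave 1177, 2201, 708, 132, 667 and 248 for these, and a minimum of 1.5-fold 3381, 3909, 549, 1167, 2263, 293, 276, 1101 and 579 for all 9, fewer by construction. Joint quantile normalization gave 1300 for H. Without experiment 0 C was 5450, D 5740, F 4549, G 2570, H 5602 and I 5407. For C 2541 of the 2693 genes remained, and for D and F all of the 3603 and 1855, which hold no array of experiment 0 and changed through the shared spread. The cause was not tested beyond the spread.

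With an estimated correlation 2, 0, 0, 4, 3, 0, 0, 0 and 0 lists were called, since camera then allows for correlated genes. fry, which tests a list by itself, gave 14 for A, 16 for B, 5 for F and 4, 9 and 1 for G to I. Without the lowest tertile of genes 6 and 8 lists were called for G and H, and 6 for G without experiment 0; the cause was not tested. Named genes kept direction and side of the threshold in 3274 of 3478 tests and single lists in 897 of 1071 tests.

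Genes called in both sets at a threshold of 0.01 were 806 down with WTp53, and 90 up and 77 down for the differences from WTp53. Without experiment 0 they were 2446, 988 and 1174.

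Leaving out single arrays, where the group of 2 is assumed to vary like the others, gave 7101 to 7871, 7625 to 9731, 1785 to 4816, 2602 to 2737, 5092 to 5474, 797 to 1434, 200 to 1318, 1272 to 3185 and 494 to 4312 genes, and 9 to 11, 9 to 11, 8 to 10, 6 to 7, 13 to 14, 10 to 12, 7 to 11, 8 to 14 and 5 to 9 lists. No named gene or list that passed changed its direction under the settings run. The share of calls that were up for D went from 53.8% to 41.6% with each array centred on its median and 46.8% with joint quantile normalization, so the direction of its majority turned. Signal over background was not measured, and dim genes were limited only by leaving out the lowest tertile.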

Other observations

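The tests of the zinc finger and small RNA genes, of experiment 0 and of the shared direction below were chosen after the results were seen; the counts of splits were planned, except those that keep pairs together.

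More zinc finger genes fell than rose with every p53 construct relative to the vector. They were taken as all symbols that start with ZNF or ZFP, a choice made after ZNF221, ZFP30 and ZNF582 stood among the largest falls. Of 514 genes 290 fell and 72 rose with WTp53 in the first set, with a median of −0.40 (camera p = 3.73e-13, p = 0.0454 with an estimated correlation). With ΔNp53:WTp53 273 fell and 74 rose (camera p = 1.31e-08, p = 0.106 with an estimated correlation). In the second set 180 fell and 48 rose with WTp53 (camera p = 1.14e-08, p = 0.105 with an estimated correlation) and 212 fell and 64 rose with tethered WTp53 (camera p = 1.53e-05, p = 0.209 with an estimated correlation). The median stayed below 0 in these 4 comparisons after joint quantile normalization and after centring on array medians. Relative to WTp53, 69 zinc finger genes rose and 11 fell with ΔNp53:WTp53 (camera p = 6.54e-04, p = 0.316 with an estimated correlation), and 32 rose and 22 fell with tethered WTp53 (camera p = 0.867, p = 0.96 with an estimated correlation). The difference of the WTp53 effect, first minus second set, had a median of −0.23, with 15 genes up and over 9 times as many down (camera p = 4.78e-11, p = 0.0662 with an estimated correlation). The difference of ΔNp53:WTp53 and tethered WTp53 had 9 up and 10 down relative to WTp53 (camera p = 0.00349, p = 0.387 with an estimated correlation) and 8 up and 46 down relative to the vectors (camera p = 2.46e-07, p = 0.139 with an estimated correlation).

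Small noncoding RNAs were lower with the tethered construct than with WTp53 of its set. Of 210 small nucleolar, Cajal body, vault and spliceosomal RNA genes, grouped after seeing VTRNA1-2 and SNORD114-3 among the largest falls, 56 fell and 0 rose with tethered WTp53 relative to WTp53, with a median of −0.21 (camera p = 3.01e-17, p = 0.00647 with an estimated correlation). With WTp53 relative to the vector of the same set 45 rose and 11 fell (camera p = 2.25e-05, p = 0.125 with an estimated correlation). Tethered WTp53 relative to the vector gave 8 up and 40 down (camera p = 0.0315, p = 0.419 with an estimated correlation). In the first set WTp53 relative to the vector gave 27 up and 40 down (camera p = 0.221, p = 0.642 with an estimated correlation). The difference of the WTp53 effect, first minus second set, had a median of −0.17, with 3 genes up and 28 down (camera p = 4.84e-07, p = 0.0738 with an estimated correlation). With ΔNp53:WTp53 relative to WTp53 8 rose and 12 fell (camera p = 0.847, p = 0.942 with an estimated correlation). The difference of the effects of ΔNp53:WTp53 and tethered WTp53 relative to WTp53 had a median of 0.19, with 18 genes up and 0 down (camera p = 1.61e-12, p = 0.0176 with an estimated correlation). Relative to the vectors it had a median of 0.04, with 6 up and 3 down (camera p = 0.372, p = 0.734 with an estimated correlation), so a difference of the constructs was seen only relative to WTp53. Of the markers of other cells, leukocyte markers were called for ΔNp53:WTp53 against WTp53 (camera adjusted p = 0.0492, adjusted p = 0.492 with an estimated correlation) and lung epithelial markers by camera in no comparison. Fibroblast and endothelial markers were not called by camera in the 6 pairwise comparisons. They were called in the difference of the WTp53 effect between the sets (camera adjusted p = 0.0394, adjusted p = 0.413 with an estimated correlation) and in that of ΔNp53:WTp53 and tethered WTp53 relative to WTp53 (camera adjusted p = 0.0293, adjusted p = 0.411 with an estimated correlation); the actin gene ACTA2 rose with WTp53 by 3.47 in the first set and 2.27 in the second. Inflammatory and senescence-associated secreted factors were called by camera in no comparison (camera adjusted p from 0.152 to 0.978), although the cytokine LIF rose by 1.36 ± 0.15 with WTp53 in the second set.

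For the comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. The real counts were 8052, 8613, 2693, 3603, 6215 and 1855, each matched by 1 split, the real one, and the highest others were 2, 1, 2346, 0, 0 and 0, in the order WTp53, ΔNp53:WTp53 and ΔNp53:WTp53 against WTp53 in the first set and WTp53, tethered WTp53 and tethered against WTp53 in the second. The 2346 came from the split that puts ΔNp53:WTp53 of experiment 0 with WTp53 of experiments 0 and 4, and the real count with the experiment as a block was 3291. Among the 4 splits that part all 3 pairs, the real one included, the highest other gave 2; the others leave pairs together. For the difference of ΔNp53:WTp53 and tethered WTp53 relative to WTp53, 1 of 100 splits reached 544, the real one, and the highest other gave 5. Relative to the vectors 2 of 100 reached 1090 and the highest other gave 2188. These splits exchange single arrays and part pairs of the first set. Among the 28 that keep these pairs 1 reached 544 and 1 reached 1090, the real one each time, and the highest others gave 0 and 1. The sets differ in spread and scale, so exchanging their arrays cannot exclude chance for the 544 or the 1090. For the 1090 the split with 2188 genes also leaves a structure of the samples open. That split exchanges ΔNp53:WTp53 of experiment 0 with tethered WTp53 of experiment e and points to a structure of the samples at experiment 0. The blocked count was 1830.

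ΔNp53:WTp53 of experiment 0 had a smaller fall of G2/M genes than experiments 4 and 5. A shift of experiment 0 shared by all its arrays is argued against, since the G2/M median of ΔNp53:WTp53 minus WTp53 within experiment 0 was −0.22 (quartiles −0.36 to −0.03), against −1.20 (−1.38 to −0.77) and −1.54 (−1.70 to −0.95). The sort for green fluorescence would remove untransfected cells; cells that passed it without the constructs stay open. The response of experiment 0 was taken on the linear scale as a fraction of that in experiments 4 and 5. Only genes over 1.5-fold in experiments 4 and 5 were used, 26 of 29 G2/M genes that fell and 45 of 69 p53 targets that rose. The median fraction was 0.42 for the G2/M genes (quartiles 0.36 to 0.49) and 0.58 for the p53 targets (quartiles 0.45 to 0.76), and these quartiles overlap. The genes were chosen by the response they are divided by, which tends to lower both fractions. A lower dose of the shortened isoform in that transfection was not tested and stays open.

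Both constructs differed from WTp53 in the same direction for many genes, among them lower oxidative phosphorylation genes and higher CHAC1, PLK3 and RAB27B. Relative to WTp53 the arrest and feedback targets had medians of −0.32, −0.05 and −0.10 with ΔNp53:WTp53 in experiments 0, 4 and 5. All were under 0, which the rule written for this test counts against a larger p53 dose in both. Single targets ranged from −1.23 to 1.27, with 6 down and 1 up, so these medians do not decide it and a larger dose stays open. That the tethered arrays hold the ΔNp53:WTp53 combination, as their transfection field reads, stays open: the 2 differences from WTp53 correlated at 0.42 across genes, against 0.79 for WTp53 between the sets, and construct and set cannot be told apart. A shared effect of joining 2 p53 units, which the names of the constructs would allow, was not tested.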
